A study of Homo sapiens with 9 samples.

How the data were processed

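RNA from 9 Huh7 samples in 3 groups of 3 was measured by poly(A), strand-specific sequencing, per the labels' protocols. The deposited table holds FPKM (fragments per kilobase of transcript, scaled to the library's depth) for 27421 genes, and its 9 sample columns were all used. HISAT, featureCounts and DESeq2 are named, without versions, per the submitters' processing notes. The genome build is not given in the sources used here, and coordinates are those of the deposited table. Of its gene IDs, 25089 occur in GENCODE release 29 and 25058 overlap the position given there. The deposited table lists 16964 genes as protein-coding, 10442 as lncRNA, 14 as artifact and 1 as ribozyme, and 7191 names are only an ID.

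Depth was recovered from the deposited FPKM of 1631 single-exon genes, whose values were whole multiples of 1 fragment within 0.1 fragments for 99.9% to 100% of 717 to 835 values per library. It was 18430000 to 23740000 fragments. Intervals for counting error were not computed, because the spread between libraries was far larger. The chi-square per degree of freedom over single-exon genes was 3.62 for the closest pair of replicates, so no pair agreed within sampling noise and all 9 were kept as separate samples. No replicate columns were identical.

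Genes with at least 1 FPKM in at least 3 libraries were tested, 11245 in all. limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) with a trend on all 9 libraries and the group as the only term. Fold changes are on that scale, which understates the change of low genes. A gene was called at a two-sided Benjamini-Hochberg adjusted p under 0.05. Contrasts were each arm against the control, the mean of both arms against the control, and shZMAT2-2 against shZMAT2-1. ZMAT2 and TRIM28 were also compared by an exact permutation test. Of 31 gene lists, 28 with at least 5 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. The lists of fibroblast, leukocyte and endothelial markers had fewer tested members and were given values only. Gene Ontology terms in the deposited table were tested by the hypergeometric distribution against 10192 annotated tested genes.

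The tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes ZMAT2 and TRIM28, and then protein-coding genes with a symbol and a mean of at least 5 FPKM in a group. These are the genes called in both arms with no overlap between control and knockdown libraries, the extremes of the difference between the arms, and up to 4 members per list with the smallest adjusted p. From that ranking the text draws on the first member of a list, or the first 4 where the list passed. Genes named outside the rule are stated as such.

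The procedure was tested on simulated data with the real means and spreads of 11245 genes, of which 200 were changed, in 20 draws. With resampled library profiles the mean contrast recovered 7.9% of genes changed by 0.5 on the log2 scale, 56.9% at 1, 94.6% at 2 and 98.8% at 3. The mean number of false calls per draw was 1 there and 6.9 with independent noise per gene. For shZMAT2-2 it was 6.85 with resampled profiles. Means of 20 draws do not bound the false calls in the real data, where regrouping the libraries gave up to 3899 genes in the mean contrast. The alternatives were another pseudocount of 0.1, no filter and a filter of 5 FPKM, 3 other scalings, a replicate block, leaving out each library, a limit of 1 on the log2 fold change, protein-coding genes only, no trend, and a fit on only the groups compared. Further alternatives chosen after seeing the data were a mitochondrial covariate, leaving out control replicate 2 and shZMAT2-1 replicate 2 together, scaling on nuclear genes, and a regression on GC content and transcript length. The mitochondrial covariate was the log2 of the summed FPKM of the 13 mitochondrially encoded genes, centred on its mean. Planned tests on raw counts were not run, since the deposited values are FPKM. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the remaining steps.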

Results

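Huh7 cells, an established line from a human hepatocellular carcinoma, were profiled by poly(A) RNA sequencing with a strand-specific library. The 9 libraries form 3 groups of 3: a control and 2 arms in which ZMAT2 was targeted, named shZMAT2-1 and shZMAT2-2 in the labels. ZMAT2 is a zinc finger protein of the spliceosome, and the stated question was whether it acts on hepatocellular carcinoma through mRNA splicing. The values are FPKM per gene for 27421 genes, so they measure the level of a gene and cannot show which of its isoforms was made. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples. The depth recovered from the values, rounded to 10000 fragments, was 18430000 to 23740000 fragments per library, at which 3 fragments on a 1 kb transcript equal 0.126 to 0.163 FPKM.

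The libraries differed in the share of fragments from the 13 mitochondrially encoded genes. It was 7.86%, 43.2% and 8.28% in control replicates 1, 2 and 3. It was 8.25%, 16.4% and 7.70% in the shZMAT2-1 replicates and 27.0%, 14.5% and 16.6% in the shZMAT2-2 replicates. The group means were 19.8% ± 20.3 (SD, n = 3), 10.8% ± 4.85 (SD, n = 3) and 19.4% ± 6.68 (SD, n = 3). The mitochondrial share thus varied within the groups as well as between them. The first principal component of the log2 values held 72.8% of the variance. Its score was highest in control replicate 2 (0.67) and shZMAT2-2 replicate 1 (0.36), which had the highest mitochondrial shares. It was lowest, at -0.38 to -0.24, in the libraries with shares of 7.70% to 8.28%, and -0.0032 to 0.10 in the rest.

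**Figure D1:**
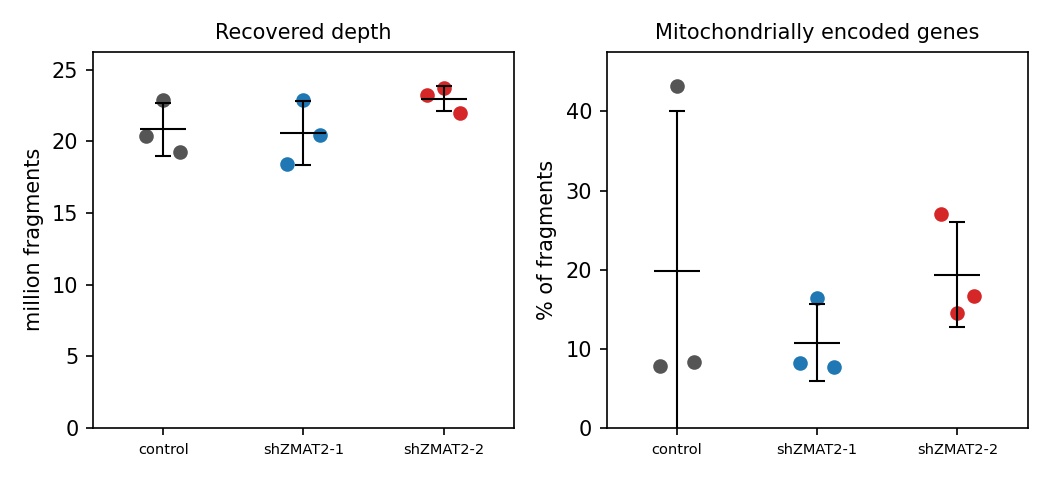
Recovered depth in fragments (left) and percent of fragments from mitochondrially encoded genes (right) for each library by group, with the group mean and SD as bars (the control SD reaches below 0 on the right and is clipped there). Depth lies between 18430000 and 23740000 fragments, and control replicate 2 stands at 43.2% mitochondrial fragments.

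The targeted gene was examined first. ZMAT2 (ENSG00000146007, chromosome 5, 140698680 to 140706686) had 36.5 ± 3.32 FPKM (SD, n = 3) in the control libraries, 13.7 ± 1.301 (SD, n = 3) in shZMAT2-1 and 21.1 ± 0.922 (SD, n = 3) in shZMAT2-2. These levels are 37.6% and 57.7% of the control mean, and the 6 knockdown libraries all lay below the 3 control libraries. The log2 fold change was -1.35 in shZMAT2-1 (limma adjusted p = 0.028) and -0.76 in shZMAT2-2 (limma adjusted p = 0.11), so the second did not pass the threshold over all genes. An exact permutation test of the 6 knockdown against the 3 control libraries gave a two-sided p of 0.0119, the smallest that 84 assignments can give. The adjusted p in shZMAT2-1 passed the threshold without control replicate 2 and missed it when any other library was left out, while the log2 fold change stayed between -1.42 and -1.297 over these fits. In shZMAT2-2 it passed without control replicate 2 (-0.84, limma adjusted p = 0.016).

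TRIM28 (ENSG00000130726, chromosome 19, 58544064 to 58550722), the corepressor that the study's title names, had 117 ± 55.5 FPKM (SD, n = 3) in the control, 157 ± 44.3 (SD, n = 3) in shZMAT2-1 and 98.7 ± 26.4 (SD, n = 3) in shZMAT2-2. The log2 fold changes of 0.53 and -0.13 had standard errors of 0.42 and did not pass (limma adjusted p = 0.81 and 1.0). The exact permutation test gave a two-sided p of 0.679. The estimate in shZMAT2-2 was -0.62 without control replicate 2, which had 52.6 FPKM against 149 and 148 in the other controls. Without control replicate 2 and shZMAT2-1 replicate 2, an alternative chosen after seeing the data, it was -0.62 and passed (limma adjusted p = 0.038). That fit sets controls of 7.86% and 8.28% mitochondrial share against shZMAT2-2 libraries of 14.5% to 27.0%. With the mitochondrial covariate, also chosen after seeing the data, the estimate in shZMAT2-2 was 0.10 (limma adjusted p = 0.65). With all 9 libraries a gene-level change of TRIM28 was not detectable, and its splicing was not measured here.

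**Figure D2:**
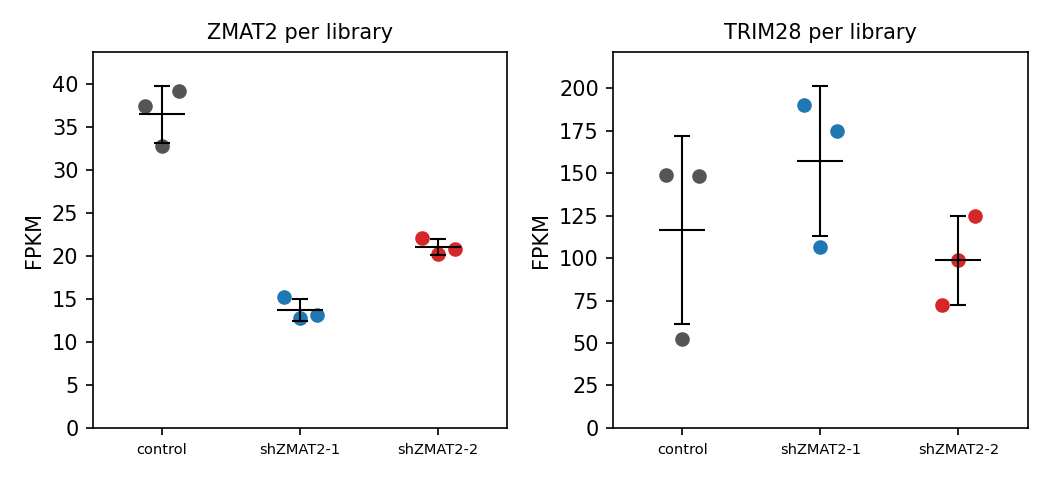
FPKM of ZMAT2 (left) and TRIM28 (right) in each library by group, with the group mean and SD as bars. The 6 knockdown libraries lie below the 3 control libraries for ZMAT2, while the groups overlap for TRIM28.

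The question of which genes change with less ZMAT2 was put to each arm and to both. In both arms 7 of 11245 tested genes passed the threshold in the same direction, 6 higher and 1 lower. This count depended on the processing: it was 0 with TPM and with only the groups compared in the fit, 59 with median-of-ratios scaling and 62 with quantile normalization. With TPM the counts for shZMAT2-1, shZMAT2-2 and the mean of the arms were 0, 0 and 1. NPPB, which encodes a natriuretic peptide (ENSG00000120937, chromosome 1, 11857464 to 11858945), rose from 32.1 ± 15.6 FPKM to 214 ± 49.3 and 142 ± 33.9 (SD, n = 3 each), with log2 fold changes of 2.82 and 2.23. CXCL1, a neutrophil-attracting chemokine (ENSG00000163739, chromosome 4, 73869393 to 73871308), rose from 10.99 ± 2.93 to 35.2 ± 2.52 and 40.1 ± 3.03 FPKM (SD, n = 3 each), with log2 fold changes of 1.62 and 1.81. IL18, a cytokine of the interleukin-1 family (ENSG00000150782, chromosome 11, 112143253 to 112164096), rose from 4.92 ± 0.987 to 15.2 ± 0.971 and 14.4 ± 0.645 FPKM (SD, n = 3 each), with log2 fold changes of 1.46 and 1.39. The other 4 genes lie below the expression limit of the naming rule and were named after their values were seen. GBP1 and GBP2, interferon-inducible guanylate-binding proteins, rose from 0.344 ± 0.0517 to 2.62 ± 0.593 and 2.62 ± 0.0772 FPKM, and from 0.600 ± 0.0352 to 1.94 ± 0.0232 and 1.72 ± 0.0815 FPKM. LAD1, a basement membrane anchoring protein, rose from 1.03 ± 0.317 to 3.88 ± 0.248 and 4.97 ± 0.955 FPKM, and CRISP3, a cysteine-rich secretory protein, fell from 1.80 ± 0.319 to 0.239 ± 0.148 and 0.226 ± 0.0553 FPKM (SD, n = 3 each).

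**Figure D3:**
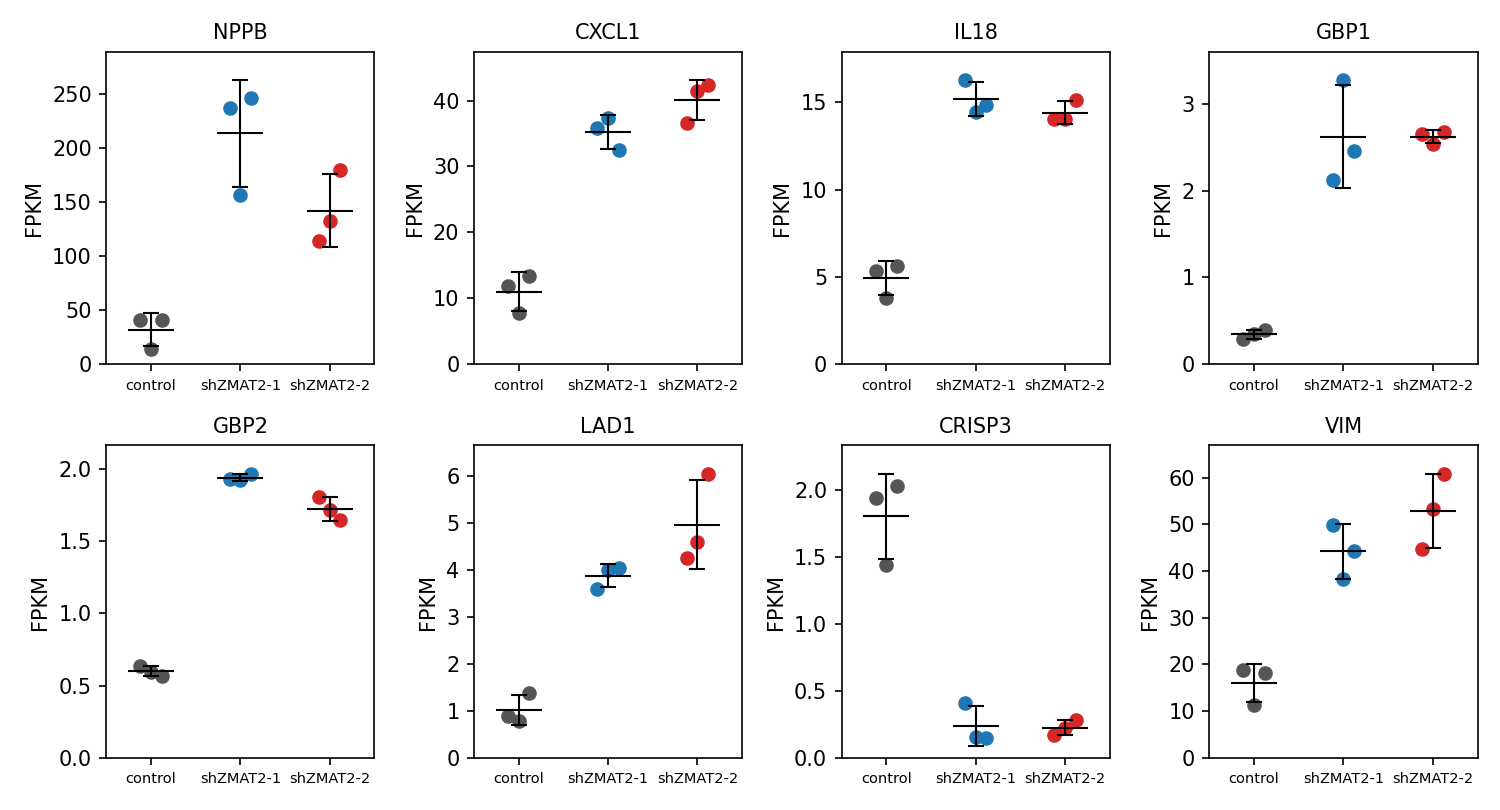
FPKM per library by group, with the group mean and SD as bars, for the 7 genes called in both arms and for VIM, called in the mean of the arms. The knockdown libraries lie above the control libraries for NPPB, CXCL1, IL18, GBP1, GBP2, LAD1 and VIM and below them for CRISP3.

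In limma's test with Benjamini-Hochberg adjustment, shZMAT2-1 had 9 genes past the threshold, 7 higher and 2 lower. shZMAT2-2 had 66, of which 57 were higher and 9 lower. All 66 had the same sign in shZMAT2-1, where 7 of them passed. For independent lists of these sizes, n1 × n2 / N gives 0.0355 genes higher and 0.0016 lower in both. Both comparisons use the same control libraries, which cannot be split into 2 parts of at least 2, so part of any agreement may come from them. Across genes, which are not independent replicates, the fold changes of the arms correlated at r = 0.24. In 100 simulations of unchanged arms against shared controls the mean was 0.40 with resampled library profiles and 0.50 with independent noise. The resampled profiles sum to 0 within a group, and some of their draws were degenerate, with r from -0.75 to 1 and up to 4560 shared calls (median 0). The covariance was 0.0190, against means of 0.0272 and 0.0438 in the simulations, so the agreement of fold changes over all genes was no greater than the mean that shared controls gave. With resampled profiles the median covariance was 0.0134, and 43 of the 100 draws were as large as the observed value. The shared calls numbered 7, and 1 of the 100 simulations with library profiles and none of the 100 with independent noise gave as many. The shZMAT2-1 count was 33 without control replicate 2 and 0 without any single one of the other 8 libraries. The shZMAT2-2 count was 270 without control replicate 2, 127 higher and 143 lower, and 0 without shZMAT2-2 replicate 2 or 3. It was 14 and 15 without control replicates 1 and 3, 26 and 19 without shZMAT2-1 replicates 1 and 3, and 8 without shZMAT2-2 replicate 1. The count shared by both arms was 31 without control replicate 2 and 0 without any other single library.

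The mean of both arms against the control gave 61 genes, 51 higher and 10 lower, and 779 genes at an unadjusted p under 0.05. In 604 of the 11245 genes, or 5.37%, the 6 knockdown libraries did not overlap the 3 control libraries. Averaged over all 84 choices of 3 libraries, this share is 2.38%. Genes are not independent replicates and the share of other choices was not computed, so 5.37% is not shown to exceed chance. Of the 604 genes, 527 were higher and 77 lower, and all 61 called genes were among them. The count was 150 without control replicate 2, 75 higher and 75 lower, 23 without control replicate 1 and 6 without control replicate 3. When control replicate 2 and shZMAT2-1 replicate 2 were both left out, an alternative chosen after seeing the data, the mean gave 196 higher and 265 lower and shZMAT2-2 759 higher and 2637 lower. Without control replicate 2 the excess of higher calls was thus lost. That fit sets controls of 7.86% and 8.28% mitochondrial share against arms of up to 27.0%. With all 9 libraries and the mitochondrial covariate, also chosen after seeing the data, 893 were higher and 203 lower. Without the covariate, the count was 30 and 18 without shZMAT2-1 replicates 1 and 3, and 16 and 15 without shZMAT2-2 replicates 2 and 3. Of 100 partitions of the 9 libraries into groups of 3, the real one included, 5 gave at least 61 genes.

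Among the NF-kB and cytokine genes, 16 were tested and all 16 had a higher estimate in the mean of the arms. Of these, 2 rose over all genes tested and 5 when adjusted over the list alone. CXCL8, another neutrophil chemokine, rose from 5.65 ± 2.54 to 20.5 ± 2.92 and 20.5 ± 0.437 FPKM (SD, n = 3 each), by 1.78 on the log2 scale (limma adjusted p = 0.014). IL32 had 12.1 ± 2.68, 27.0 ± 5.14 and 26.5 ± 4.59 FPKM (limma adjusted p = 0.053), and CXCL5 had 19.5 ± 5.59, 30.1 ± 2.10 and 27.4 ± 1.17 FPKM (limma adjusted p = 0.45). In the mean of the arms NPPB, VIM and CXCL8 missed the threshold without control replicate 3, without shZMAT2-1 replicate 3 and without shZMAT2-2 replicate 2 or 3, with adjusted p values from 0.052 to 0.059. CXCL8 also missed it without shZMAT2-1 replicate 1 (0.051), and GBP2 without control replicate 3 (0.058). The list as a whole lay above the other genes in limma's camera with its preset correlation (adjusted p = 1.0e-07). With an estimated correlation the adjusted p was 0.99.

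Of the extracellular matrix and epithelial-mesenchymal transition genes, 14 of 17 had a higher estimate, 2 rose over all genes tested and 5 adjusted over the list alone. VIM, the intermediate filament vimentin, rose from 16.1 ± 4.15 to 44.2 ± 5.79 and 52.9 ± 7.97 FPKM (SD, n = 3 each), by 1.56 on the log2 scale. TAGLN, an actin-binding protein of contractile cells, rose from 1.93 ± 1.14 to 12.4 ± 4.05 and 8.07 ± 2.96 FPKM. THBS1 had 8.28 ± 2.497, 14.1 ± 2.75 and 24.7 ± 5.77 FPKM (limma adjusted p = 0.081), and CDH1, the epithelial cadherin, 5.43 ± 1.37, 7.19 ± 0.842 and 9.21 ± 0.748 FPKM (limma adjusted p = 0.39). The camera adjusted p was 3.2e-05 with the preset correlation and 0.99 with an estimated one. In the immediate early list 1 of 24 genes rose, CCN1, a matricellular protein, from 20.1 ± 2.97 to 38.7 ± 4.00 and 44.9 ± 5.37 FPKM (limma adjusted p = 0.033). CCN1 passed when control replicate 2 was left out and missed when any other library was. TAGLN passed without the second replicate of the control or of shZMAT2-1 or the first of shZMAT2-2, and missed in the other 6 such fits. The genes higher in the mean of the arms, of which 50 of 51 were annotated, were enriched for 17 of 2718 Gene Ontology terms. These include the cellular response to interleukin-1, with 6 of 38 background genes (adjusted p = 6.8e-05), and basement membrane, with 5 of 45 (adjusted p = 0.0011). No term passed for the 10 lower genes.

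Other lists moved with camera's preset correlation while no or 1 member passed. Replication-dependent histones lay lower (25 genes, adjusted p = 2.8e-06, and adjusted p = 0.99 with an estimated correlation) with none past the threshold. H4C8 had 14.5 ± 2.28, 10.4 ± 0.618 and 10.8 ± 0.638 FPKM and H2BC4 11.4 ± 3.62, 7.98 ± 1.22 and 6.48 ± 0.953 FPKM, and these genes belong to near-identical families that counting may split. The histone list was set up beforehand as a measure of RNA quality, and the libraries were poly(A) selected. Lower values of the list therefore do not show lower histone expression in the cells. Ribosomal protein genes lay lower (70 genes, adjusted p = 1.1e-04, and adjusted p = 0.99 with an estimated correlation), but the arms went opposite ways. In shZMAT2-1 66 of 70 had a higher estimate (median 0.30, camera adjusted p = 0.79), and in shZMAT2-2, the arm with the higher mean mitochondrial share, 2 of 70 did (median -0.42, camera adjusted p = 1.7e-11). RPL26 was at 11.03 ± 3.97, 7.90 ± 0.147 and 9.09 ± 1.19 FPKM. Heat shock genes lay lower (19 genes, adjusted p = 0.0025, and adjusted p = 0.99 with an estimated correlation), with HSPA8 at 451 ± 60.9, 311 ± 18.2 and 367 ± 23.0 FPKM. Fatty acid and lipid synthesis genes lay lower (19 genes, adjusted p = 0.0040, and adjusted p = 0.99 with an estimated correlation), with GPAM, the first enzyme of glycerolipid synthesis, at 7.56 ± 2.77, 4.21 ± 0.647 and 3.80 ± 0.861 FPKM. Secreted proteins of hepatocytes lay lower (36 genes, adjusted p = 0.014, and adjusted p = 0.99 with an estimated correlation, 1 gene past the threshold) although their median log2 fold change was 0.03, and named members went both ways. SERPIND1 had 98.4 ± 3.89, 137 ± 16.04 and 172 ± 10.5 FPKM and A2M 241 ± 73.2, 163 ± 8.06 and 118 ± 18.6 FPKM. Genes named ZNF (301 genes, adjusted p = 0.039, median 0.04) and endoplasmic reticulum chaperones (24 genes, adjusted p = 0.049) lay lower, and interferon-stimulated genes (13 genes, adjusted p = 0.049, none past the threshold) lay higher. For these 3 lists too the adjusted p was 0.99 with an estimated correlation. Over the 28 lists and 3 contrasts, 30 of 84 tests passed with the preset correlation, none with an estimated correlation and none with fry. Of the 10 lists called in the mean of the arms, 5 passed in every fit without 1 library. The ribosomal protein list missed without shZMAT2-1 replicate 2 (adjusted p = 0.29), and the hepatocyte list without control replicate 3 or shZMAT2-1 replicate 2 (0.054 and 0.073). The ZNF, chaperone and interferon lists missed in 4, 6 and 5 of the 9 fits. RPL26 had 15.6 FPKM in control replicate 2, the library with the highest mitochondrial share, and 8.49 and 8.99 in the other controls. RPS12 and RPLP1, also ribosomal protein genes, went the other way there. RPS12 had 147 FPKM against 834 and 794, and RPLP1 23.3 against 133 and 128. The mean of RPL26 was also lower in shZMAT2-1, where 66 of 70 members had a higher estimate, so RPL26 does not stand for the list.

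The splicing, cell cycle and p53 lists did not pass in the mean of the arms. The camera adjusted p was 0.82 for tri-snRNP and B-complex proteins (29 genes), 0.52 for SR proteins and hnRNPs (32 genes) and 0.90 for transcripts sensitive to nonsense-mediated decay (20 genes). It was 0.26 for TRIM28 and heterochromatin partners, 0.053 for G1/S and DNA replication, 0.49 for G2/M and mitosis and 0.26 for p53 targets. None of these lists held a gene past the threshold over all genes. MYBL2, a cell cycle transcription factor, had 120 ± 7.39, 160 ± 6.98 and 160 ± 12.9 FPKM (limma adjusted p = 0.63), and PLK2 3.98 ± 1.33, 7.23 ± 0.410 and 6.74 ± 1.16 FPKM (limma adjusted p = 0.23). Of the 26 liver transcription factor and metabolism genes (camera adjusted p = 0.96) none passed over all genes, and 3 higher and 2 lower passed adjusted over the list alone. ARG1, the urea cycle arginase, had 10.1 ± 1.43, 5.37 ± 0.828 and 5.73 ± 0.563 FPKM (limma adjusted p = 0.079, and 0.017 without control replicate 2). The other lists did not pass in the mean either, with camera adjusted p values of 0.051 for immediate early and AP-1 genes, 0.094 for the ATF4 and amino acid response, 0.14 for mitochondrially encoded genes, 0.18 for cholangiocyte markers and 0.23 for nuclear oxidative phosphorylation. The values were 0.42 for oncofetal and carcinoma markers, 0.45 for apoptosis regulators, 0.49 for ribosome biogenesis and MYC targets, 0.66 for glycolysis and hypoxia, and 0.82 for cholesterol synthesis and uptake. For the tri-snRNP, SR protein, decay-sensitive, TRIM28 partner, ATF4, oncofetal, oxidative phosphorylation, glycolysis and cholesterol lists the median log2 fold change lay above 0 while camera's direction was lower. In single arms some of these lists passed with the preset correlation, each with an adjusted p of 0.99 with an estimated correlation. In shZMAT2-1, G1/S genes (camera adjusted p = 0.0040, 41 of 43 higher) and p53 targets (0.044, 24 of 25 higher) lay higher and mitochondrially encoded genes lower (2.9e-04, 0 of 13 higher). In shZMAT2-2, immediate early genes (0.017) and cholangiocyte markers (0.017) lay higher, and oxidative phosphorylation (2.3e-04), ATF4 (0.034) and cholesterol genes (0.042) lower. Of the 18 lists not called in the mean, 7 passed in at least 1 fit without 1 library. Mitochondrially encoded genes passed as higher without control replicate 2 (adjusted p = 6.9e-08) and as lower without control replicate 1 or 3 (3.7e-07 and 3.3e-06), shZMAT2-1 replicate 2 (0.025) or shZMAT2-2 replicate 1 (0.0096). Without control replicate 2, glycolysis (0.036) and ATF4 (0.0078) passed as lower, and cholangiocyte markers (0.031) and immediate early genes (0.0052) as higher. G1/S genes passed as higher without control replicate 1 or 3 (0.0093 and 0.00999), shZMAT2-1 replicate 2 (0.047) or shZMAT2-2 replicate 1 (0.037). Oxidative phosphorylation passed as lower without shZMAT2-1 replicate 1 or 3 (0.014 and 0.043), and ATF4 without shZMAT2-1 replicate 1 or shZMAT2-2 replicate 3 (0.037 and 0.044). Immediate early genes passed as higher without shZMAT2-1 replicate 3 (0.032) or shZMAT2-2 replicate 1 or 2 (0.046 and 0.047).

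Whether the arms differ from each other was tested directly. No gene passed in shZMAT2-2 against shZMAT2-1 in limma's test, the smallest adjusted p was 0.66, and 465 genes had an unadjusted p under 0.05. The highest and lowest log2 differences by the naming rule belonged to MT-ATP8, MT-ND4L, MRPL12 and TOMM7, none of which passed. MRPL12 had 25.1 ± 17.3 FPKM in shZMAT2-1 and 5.11 ± 1.41 in shZMAT2-2, and TOMM7 23.3 ± 14.9 and 5.45 ± 0.762 FPKM (SD, n = 3 each). Without control replicate 2 and shZMAT2-1 replicate 2, an alternative chosen after seeing the data, 4761 genes passed. A p that misses the threshold does not show that the arms act alike.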

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

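The tests of ZMAT2 knockdown as a source of the library spread, and all 3 tests on the cytokine and matrix genes, were chosen after the results were seen, and the mitochondrial covariate was added after seeing the data.

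A test of the difference between the arms set 8 gene lists apart in shZMAT2-2 against shZMAT2-1 with camera's preset correlation. Lower lists were ribosomal proteins (adjusted p = 8.0e-11), nuclear oxidative phosphorylation (1.2e-06), cholesterol biosynthesis (3.4e-04), G1/S and DNA replication (0.036) and transcripts sensitive to nonsense-mediated decay (0.036). Higher lists were mitochondrially encoded genes (1.0e-04), cholangiocyte markers (0.011) and extracellular matrix genes (0.023). With an estimated correlation none passed, with adjusted p values of 0.67 for cholangiocyte markers and 0.96 for the others. The mean mitochondrial share was 10.8% in shZMAT2-1 and 19.4% in shZMAT2-2. With the mitochondrial covariate the median log2 difference went from -0.68 to -0.17 for ribosomal proteins, from -0.66 to -0.18 for oxidative phosphorylation and from -0.50 to -0.12 for cholesterol. For mitochondrially encoded genes it went from 0.94 to 0.0026. Their fall, and the loss of their call, follow from the construction, since the covariate is the log2 summed FPKM of these same genes. For the lists of nuclear genes the median also changed. The median went from -0.25 to 0.02 for G1/S and from -0.43 to 0.01 for decay-sensitive transcripts. For cholangiocyte markers it was 0.23 and 0.22, and for matrix genes 0.25 and 0.31. With the preset correlation, ribosomal proteins (6.6e-14), oxidative phosphorylation (3.0e-07), cholesterol (3.5e-05), cholangiocyte markers (0.012) and matrix genes (0.032) still passed with the covariate. Mitochondrially encoded genes, whose direction turned to lower (0.27), G1/S (0.21) and decay-sensitive transcripts (0.059) did not. Heat shock proteins (0.0027), glycolysis and hypoxia (0.0066) and replication-dependent histones (0.030) passed only with it, as higher. With an estimated correlation none passed with the covariate either (0.80 at the lowest), so the covariate did not settle what sets these lists apart.

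Control replicate 2 and shZMAT2-1 replicate 2 departed alike from the other libraries of their groups, with a Spearman rho of 0.84 across 6049 nuclear genes, which are not independent replicates. Another library, shZMAT2-2 replicate 1 (27.0% mitochondrial), departed with them, and its deviations from the group mean correlated at r = 0.81 with control replicate 2 and 0.68 with shZMAT2-1 replicate 2, where those 2 gave 0.78. A loss of reads to mitochondrial genes alone would lower all nuclear genes by 1 factor, and rho was 0.83 after a regression on GC content and transcript length (15.2% and 39.6% of the variance), which argues against either as the whole cause. Knockdown cannot account for the control library. Its mitochondrial share of summed FPKM (80.8%) exceeded the highest knockdown share (65.9%) by 14.85 percentage points. As shares of fragments these 2 libraries had 43.2% and 27.0%. The labels give no batch, so a difference in RNA handling or library preparation stays open.

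Of 16 cytokine genes 1, 2 and 2 were called higher in shZMAT2-1, shZMAT2-2 and their mean, and of 17 matrix genes 0, 2 and 2, while neither list passed with an estimated correlation (adjusted p = 0.99). With the mitochondrial covariate 100% of the 51 genes called higher in the mean of the arms were still called higher. This cannot decide on the library spread as their cause. The covariate hardly differed between the control and the mean of the arms (median log2 fold change of mitochondrially encoded genes -0.006). It thus left estimates nearly unmoved (NPPB 2.52 and 2.49, CXCL1 1.715 and 1.703) while it raised the number of calls. Fibroblasts would bring type I and III collagens, but the summed COL1A1, COL1A2 and COL3A1 were higher by 0.346 FPKM where VIM was higher by 32.5 FPKM. A general interferon response stays open. None of the 13 tested genes of the interferon-stimulated list passed, and 3 passed with the covariate. GBP1 and GBP2, interferon-inducible genes outside these 13, were called in both arms. Genes called higher in the mean of the arms were also enriched for the cellular response to interferon-gamma. They held 5 of its 40 background genes, GBP1 and GBP2 among them (hypergeometric adjusted p = 8.3e-04). Lower ZMAT2 is the biological explanation that the design names, and it was not tested apart from other effects of the hairpins.

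Chance was weighed by regrouping the libraries. For the mean of the arms, 5 of 100 partitions gave at least the real 61 genes, so chance cannot be excluded for that count. The highest other partition gave 3899, many times the real count, and the others that reached 61 gave 2895, 3085 and 2956. Fitted with the mitochondrial covariate, these other partitions gave 0 genes, where the real grouping gave 1096. Their calls thus depended on that covariate, which was chosen after seeing the data. What else set them apart was not tested. For calls shared by both arms, 2 of 100 gave at least the real 7 (highest other 9). For gene lists 1 of 100 gave the real 30, and the other partitions gave 4 to 29. Both shares lie under 0.05, so the real totals are extreme among these partitions. That does not exclude chance for the lists or genes themselves, since every partition called lists with the preset correlation. Leaving out 1 library moved the real list count to between 26 and 36. The margin for lists is 1, and none of the 30 passes with an estimated correlation. The shared count was 0 without any single library other than control replicate 2. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. There the real counts were 9, 66 and 0 for shZMAT2-1, shZMAT2-2 and the difference of the arms, reached by 1, 1 and 10 of the splits, and the highest other was 0 in each.

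More genes were called with the mitochondrial covariate, 1096 in place of 61 for the mean of the arms. Of 100 partitions fitted with the same covariate, 4 gave as many, the real one included, and the highest other gave 2662. This argues against a gain from the covariate alone, although a margin of 4 in 100 is narrow and the covariate was chosen after seeing the data.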

How the results depend on the processing

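The counts of called genes depended on the processing, while the direction of the genes called in both arms did not change in the mean of the arms under any alternative run. The cause of each change was not tested unless its construction shows it. In order, the values below are for shZMAT2-1, shZMAT2-2, both arms in the same direction, and the mean of the arms (main 9, 66, 7 and 61). A filter of 5 FPKM, which tests fewer genes, gave 4, 15, 2 and 25. Rescaling to TPM gave 0, 0, 0 and 1. TPM divides by the summed FPKM, which was 604472 in control replicate 2 and 289939 and 296894 in control replicates 1 and 3. Mitochondrially encoded genes held 80.8% of that sum in control replicate 2, so by construction this scaling carries their spread over to the nuclear genes. Median-of-ratios scaling gave 77, 193, 59 and 213, and quantile normalization 79, 195, 62 and 209. With only the groups compared in the fit the first 3 counts were 0. A log2 limit of 1 left 43 genes in shZMAT2-2 and 35 in the mean. Protein-coding genes alone gave 16 in shZMAT2-1 and 13 in both, and limma without a trend 5 and 3. Leaving out each library gave 0 to 33, 0 to 270, 0 to 31 and 6 to 150.

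Alternatives added after seeing the data were as follows. The mitochondrial covariate gave 419, 1107, 318 and 1096. Nuclear scaling gave 55, 161, 44 and 180, and GC and length regression 22, 89, 19 and 96. Without control replicate 2 and shZMAT2-1 replicate 2 the counts were 140, 3396, 100 and 461, and 4761 genes differed between the arms, where all other settings gave 0. This leaves low mitochondrial shares in 2 groups and high ones in shZMAT2-2. The median log2 fold change of all genes in shZMAT2-1 was 0.16 as deposited, 0.37 with TPM, 0.03 with median-of-ratios, -0.03 with nuclear scaling and 0.00 with quantile normalization. The share of higher calls as deposited and with median-of-ratios, nuclear and quantile scaling was 83.6%, 69.0%, 71.1% and 69.9% in the mean, and 86.4%, 70.5%, 75.2% and 68.2% in shZMAT2-2. In shZMAT2-1 it was 77.8% as deposited and 67.3% with nuclear scaling. The excess was lost without control replicate 2, with 75 higher and 75 lower in the mean and 127 and 143 in shZMAT2-2. Without the 2 libraries it turned, to 196 and 265 and to 759 and 2637.

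The replicate numbers did not pair the samples across all 3 groups. Between control and shZMAT2-1 the same-number pairs had correlations of 0.61, 0.78 and 0.69, but control replicate 1 had 0.68 with shZMAT2-1 replicate 3. Of 9 same-number pairs, 6 had a correlation of deviations over 0.1, the lowest was -0.76, and 3 libraries correlated best with their own number. A replicate block gave 13, 52, 9 and 58 genes.

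ZMAT2 in shZMAT2-1 was -1.17 with TPM, where its adjusted p missed the threshold, and -1.42 to -1.297 without single libraries. In shZMAT2-2 it passed with the covariate (-0.74) and without the 2 libraries (-0.84), with a range of -0.84 to -0.71 without single libraries. TRIM28 in shZMAT2-2 turned to 0.10 with the covariate, passed at -0.62 without the 2 libraries, and ranged from -0.62 to 0.12 without single libraries. In the mean of the arms TRIM28 was -0.17 without the 2 libraries and -0.29 to 0.45 without single ones. MT-ND4L was 0.59 without the 2 libraries and -0.96 to 0.83 without single ones. Its difference between the arms was -0.039 with the covariate, which is built from it and the other mitochondrially encoded genes. PDIA3 was -0.055 without the 2 libraries and -0.056 to 0.31 without single ones, ALDOC -0.054 to 0.69 and ISG15 -0.072 to 0.70. TRIM28, MT-ND4L, PDIA3, ALDOC and ISG15 were not called in the main test.

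Lists were rerun under each alternative for the mean of the arms, where none of the 10 lists called in the main test turned. For others, the value is the list's mean moderated statistic minus that of other genes. With no filter it turned to 0.18 for tri-snRNP proteins, 0.031 for SR proteins, 0.19 for transcripts sensitive to nonsense-mediated decay, 0.15 for cholesterol and 0.096 for glycolysis. With the covariate these were 0.033 for tri-snRNP, 0.15 for decay-sensitive transcripts, -0.0014 for liver factors and 0.095 for cholesterol. A filter of 5 FPKM gave 0.066 for decay-sensitive transcripts and -0.052 for liver factors. Median-of-ratios gave 0.10 for decay-sensitive transcripts and 0.019 for cholesterol. Quantile normalization gave 0.090 for decay-sensitive transcripts, -0.037 for liver factors and 0.047 for mitochondrial genes. Nuclear scaling gave 0.15 for decay-sensitive transcripts, -0.026 for liver factors and 0.037 for cholesterol. GC and length regression gave 0.018 for decay-sensitive transcripts and -0.043 for liver factors, and the replicate block 0.0094 for decay-sensitive transcripts. Mitochondrial genes stood at 2.67 without the 2 libraries. The ranges without single libraries were -0.14 to 0.060 for tri-snRNP, -0.41 to 0.12 for decay-sensitive transcripts, -0.084 to 0.28 for liver factors, -0.65 to 0.17 for cholesterol, -0.73 to 0.061 for glycolysis, -0.52 to 0.21 for oxidative phosphorylation and -1.44 to 2.35 for mitochondrial genes.

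Over all alternatives, the named genes kept direction and side in 1232 runs, lost the call in 48, gained it in 125 and turned in 9. The lists did so in 458, 26, 35 and 41. Most of the named genes, and 18 of the 28 lists, were not called in the main test. A run that left these uncalled in the same direction counts as kept, and only called ones could lose a call.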

Other observations

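All tests in this part were chosen after the results were seen. With the mitochondrial covariate, genes higher in the mean of the arms were enriched for 84 Gene Ontology terms and lower genes for 8. Higher genes included 44 of 164 genes of the collagen-containing extracellular matrix (adjusted p = 2.8e-09), 66 of 330 of focal adhesions (1.1e-08) and 20 of 48 of stress fibers (3.0e-07). Lower genes included 10 of 64 of blood microparticles (2.8e-04), 6 of 21 of the acute-phase response (8.5e-04) and also 15 of 164 of the collagen-containing extracellular matrix (2.8e-04), so that matrix term was enriched in both directions.

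Markers of other cell types stayed low with a few exceptions. COL1A1 had a mean of 0.0879, 0.145 and 0.0825 FPKM in control, shZMAT2-1 and shZMAT2-2, PTPRC 0.0152, 0.00560 and 0, and PECAM1 1.46, 1.06 and 0.697. LYZ, a lysozyme that the leukocyte list holds, had 104, 66.5 and 51.2 FPKM. KRT19, a keratin of cholangiocytes that is also in the oncofetal list, had 11.2, 18.4 and 15.8 FPKM and did not pass.

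A first hypothesis is that targets of the transcription factors SRF and MRTF rise. Of 25 tested genes in a list written for this test, 6 rose and 21 did with the covariate. The 19 genes not called had a median log2 fold change of 0.65, at percentile 100 of 10000 random lists matched on expression. A list of 22 YAP and TEAD targets had 18 tested genes, of which 4 rose. With the covariate 10 were called higher and 1 lower. Its 14 genes not called had a median of 0.47, also at percentile 100. These percentiles decide nothing: the lists were written after the called genes were seen, the members were split by their call, and random genes do not share the correlation of a list. Whether these targets rise as groups stays open, and CCN1 is in both lists.

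A second hypothesis is that the arm with less ZMAT2 left changes more. shZMAT2-1 kept 37.6% of the control level and shZMAT2-2 57.7%. Of the 61 genes called in the mean of the arms, 12, ZMAT2 among them, had the larger change in shZMAT2-1, so the prediction failed for this count. The count cannot decide on dose, since the genes are not independent replicates. The 2 arms also differ in hairpin and in mean mitochondrial share (10.8% and 19.4%). No gene differed between the arms in limma's test (465 at an unadjusted p under 0.05). Without control replicate 2 and shZMAT2-1 replicate 2, an alternative chosen after seeing the data, 4761 genes did, so the comparison of the arms depends on these libraries.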
